A study of Homo sapiens with 3 samples.

How the data were processed

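Gene expression was measured in single cells of 3 libraries, 1 per group, from human acute lymphoblastic leukaemia blasts of bone marrow. The groups were fresh blasts, a DC culture (7 days with IL-4 and GM-CSF) and a macrophage culture (7 days with M-CSF, IL-3 and GM-CSF). The labels call the first library freshly isolated, while the extraction text shared by all 3 libraries speaks of cells from culture, and the treatment label was followed here. The libraries were made with the 10x Genomics single cell 3' kit, v3.1 chemistry, per the labels' protocols. The authors deposited raw UMI counts per gene and cell barcode, made with Cell Ranger 6.1.1 per the file headers and on hg38 per the submitters' processing notes. The annotation release behind these counts is not given in the sources used here. Each table held 36601 genes and had been reduced to called cells, with at least 501, 502 and 507 UMIs per barcode in the fresh blasts, the DC culture and the macrophage culture. Gene positions were taken by gene ID from GENCODE release 29 on the same build.

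Before the data were examined, the comparisons, the gene and marker lists, the rule for naming genes and the alternatives were fixed, except where stated otherwise. Cells with at least 500 detected genes and at most 15% mitochondrial UMIs were kept. In the fresh blasts, the DC culture and the macrophage culture 244, 144 and 208 barcodes failed the first limit, 467, 236 and 358 the second, and 232, 124 and 186 of these failed both. Doublets were called per library with Scrublet, as included in scanpy, with exact neighbours and otherwise default settings. Called doublets were kept, and their removal was tried as an alternative.

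Counts were summed over the kept cells of each library and divided by the library's total to give CPM. Ratios are of CPM, with fewer than 3 counts set to 3. Genes were compared for the number at least 4-fold apart if they had at least 50 CPM in the higher library. Receptor gene segments, sex-linked genes that could describe a person and haplotype-dependent genes were left out of these counts. Mitochondrial and ribosomal protein genes and clone-based names stayed in them and in the random lists below. The 15 gene lists, fixed from general knowledge of the cell types and cytokines, covered B-cell precursor identity, myeloid transcription factors, macrophage, dendritic cell, MHC class II and class I presentation, costimulation and checkpoint ligands, cytokines and chemokines, phagocytosis and lysosome, IL-4 response, lipid handling and cholesterol, cell cycle, interferon response, apoptosis and p53 targets, and stress and dissociation. Some genes stand in several lists. A list's median log2 ratio was taken over members with at least 5 CPM in either library and set among 10000 random lists of equal size drawn from 20 bins of mean expression. No p-value was computed, because cells of 1 library are not replicates.

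The genes named for each comparison were the 10 with the highest and the 10 with the lowest ratio. They were taken among genes with at least 100 CPM in the higher library. The exclusions above held for them, and mitochondrial and ribosomal protein genes, clone-based names and LINC names were left out as well. From each list the 4 members with the highest CPM in either library and the member with the largest change in each direction were added. IL4R, CSF2RA, CSF2RB, CSF1R, IL3RA and 10 key molecules (CD14, ITGAM, CD80, CD86, CD40, CD1C, CD163, MRC1, CSF1R and SPI1) were named in every comparison. Some genes that these rules pick are not reported here. The genes named for comparisons within a class, and those named for clusters and in the closing section, were chosen after their values were seen.

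For clustering, counts were scaled to 10000 per cell and log-transformed, 2000 highly variable genes and 30 principal components were taken, and a shared-neighbour graph of 15 nearest neighbours was partitioned with the Leiden method at resolution 1, all libraries together and without batch correction. A cluster took the name of the marker list, among 13, with the highest mean excess of detection over the median cluster. It needed at least 3 markers in at least 25% of its cells, and no more markers of another class than of its own among its 10 leading genes by fold with 50 CPM added. Monocyte/macrophage-like and dendritic cell-like clusters were joined as myeloid-like. A cluster whose cells had a median UMI count below that of their own library divided by 3, with no own marker among the leading genes, stayed unnamed. This rule on UMIs, with the way its ratio is taken, was set after the data were seen, and it kept clusters 22, 25 and 27 unnamed. Classes were compared between libraries only with at least 100 cells in both, which left out the B-lymphoid-like cells of the macrophage culture.

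For shares of cells with a UMI, each cell was thinned to 2000 UMIs by drawing without replacement, and shallower cells were left out. Cells with both kinds of transcripts had UMIs of at least 2 of 8 B-lymphoid and at least 2 of 8 myeloid markers after thinning. Intervals are exact at the 95% level. Because the libraries hold from 111515130 to 234804794 UMIs, counting error is small for abundant genes, and variation between separate cultures could not be estimated.

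Alternatives to the scaling (median-of-ratios factors over genes with at least 10 counts in every library, TMM factors from edgeR, totals without mitochondrial and ribosomal protein genes), the cell filter, the doublets, the weight of each cell, the low-expression filter, the clustering and the thinning were run for the results they bear on. After the data were seen 2 more were added, the cultures' myeloid-like cells alone and all libraries without unnamed clusters and other cell types. The fold and list computations were tested on simulated data with 100 genes at 8-fold and 100 at 2-fold among 2760, 2780 and 2665 genes for the DC culture over the fresh blasts, the macrophage culture over the fresh blasts and the macrophage culture over the DC culture. In each comparison 100% of the 8-fold genes passed the 4-fold limit, and 0 of the 2-fold genes and 0 other genes did. A list of 2-fold genes had medians of 1.00, 0.99 and 0.98. A list of genes left as they were had medians of -0.01, -0.02 and -0.01, at the 43.7, 0.2 and 61.9 percentiles, so a percentile far from the middle can go with a median close to 0 and was read only beside its median. The work was done with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and with R 4.3.3 and edgeR 4.0.16 for TMM factors.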

Results

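Droplet-based single-cell RNA sequencing was done on 3 libraries of human acute lymphoblastic leukaemia blasts from bone marrow, 1 library per group. The fresh blasts were labelled as freshly isolated. The DC culture was kept for 7 days with IL-4 and GM-CSF, cytokines used to derive dendritic cells (DCs) from monocytes. The macrophage culture was kept for 7 days with M-CSF, IL-3 and GM-CSF, cytokines that act on myeloid cells. The series is about turning cancer cells into antigen presenting cells, and the labels call both cultures reprogrammed. Each culture was compared with the fresh blasts, and the cultures were compared with each other. No culture without these cytokines was analysed here, so cytokines, time in culture and handling differed together between the cultures and the fresh blasts. With 1 library per group there were no replicates and no replicate check, so every difference describes these libraries and no test was run.

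The deposited tables held 8625 barcodes for the fresh blasts, 11274 for the DC culture and 5937 for the macrophage culture. Their total counts of unique molecular identifiers (UMIs) were 111515130, 234804794 and 164775606. Cells with at least 500 genes and at most 15% mitochondrial UMIs were kept, which left 8146 fresh cells, 11018 cells of the DC culture and 5557 of the macrophage culture. The median kept cell had 11612 UMIs in the fresh library, 18312 in the DC culture and 29081 in the macrophage culture. Ribosomal protein genes took 26.8% of the UMIs of the fresh cells, 16.7% in the DC culture and 15.9% in the macrophage culture. Median mitochondrial shares were 5.18%, 2.91% and 4.29% in the same order. Expression is given as CPM, a gene's counts per 1e6 UMIs of a library's kept cells. Brackets after a value hold its 95% interval, exact Poisson for sums of counts and exact Clopper-Pearson for shares of cells, and both cover counting error only. Sums of at least 1000 counts had bounds within 6.33% of the value and are printed without them.

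Nearly all fresh cells lay in clusters named from B-lymphoid markers, and most cells of both cultures in clusters named from myeloid markers. Named cell by cell from thinned markers, 78.1% of the fresh cells were B-lymphoid-like. B-lymphoid-like clusters held 99.2% (99.03 to 99.4) of the fresh cells. No fresh cell lay in a myeloid-like cluster, and the limit of 3 cells set for a count of 0 is 0.0368% of 8146 cells. That holds for this clustering, and the other settings tried gave up to 1.29% myeloid-like fresh cells. In the DC culture 71.8% (70.996 to 72.7) of the cells were myeloid-like, a class that joins macrophage-like and dendritic cell-like clusters, and 3.19% (2.87 to 3.53) were B-lymphoid-like. The macrophage culture had 71.1% (69.9 to 72.3) myeloid-like and 1.71% (1.39 to 2.09) B-lymphoid-like cells. Whether the myeloid-like cells of the cultures came from blasts or from other marrow cells was not tested. Mast cell, basophil or eosinophil-like cells made up 2.83% (2.53 to 3.16) of the DC culture and 2.68% (2.27 to 3.14) of the macrophage culture. Granulocyte precursor-like cells made up 2.39% (2.11 to 2.69) and 5.58% (4.99 to 6.21). Both of these classes had 0 fresh cells. The granulocyte precursor-like share depended on the clustering and the cells used. It ran from 1.38% to 2.396% in the DC culture and from 1.303% to 5.65% in the macrophage culture. Clusters left unnamed held 0.761% (0.584 to 0.975) of the fresh cells. In the cultures they held 19.7% (19.01 to 20.5) of the DC culture and 18.97% (17.9 to 20.02) of the macrophage culture. The small B-lymphoid-like shares of the cultures depended on the clustering. They ran from 0.0908% to 7.44% in the DC culture and from 0% to 3.603% in the macrophage culture across the settings tried.

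**Figure D1:**
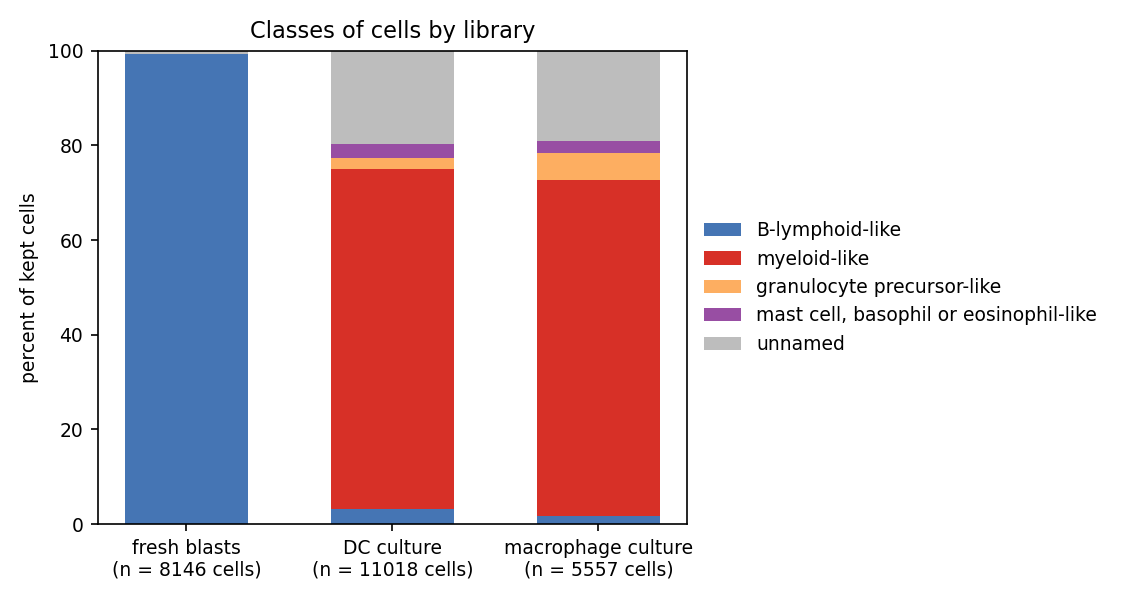
Share of the kept cells (percent, vertical axis) in each cell class for the fresh blasts, the DC culture and the macrophage culture, 1 library each. The fresh library was 99.2% B-lymphoid-like, and the cultures were 71.8% and 71.1% myeloid-like.

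Nearly all B-lymphoid-like cells of the fresh library lay in clusters 0, 9, 10, 11, 15, 17, 20 and 21, whose leading genes included DNTT, VPREB1, IGLL1, MME and CD79A. Nearly all B-lymphoid-like cells of the cultures lay in another cluster, number 18, led by MAL, LTB, MS4A1 and JCHAIN. Myeloid-like cells of the DC culture lay mostly in dendritic cell-like clusters 2, 5, 8, 12, 13 and 23, with CCL17, CCL22, CD1B, CD1E or CD207 among the leading genes of most, and in the cycling macrophage-like cluster 3. Those of the macrophage culture lay mostly in the dendritic cell-like cluster 1 (CCL19, EBI3, CCR7, LAMP3), the macrophage-like clusters 6 (CCL8, CTSL, GPNMB) and 14 (SPP1, IL1B, CD14), and cluster 3. Cluster 16, led by PRG2, CLC, CPA3 and HDC, was mast cell, basophil or eosinophil-like. Clusters 19 (ELANE, MPO, PRTN3) and 24 (S100A8, S100A9, PRTN3, ELANE) were granulocyte precursor-like. Cluster 24 took its name on a tie among its 10 leading genes. PRTN3 and ELANE are granulocyte precursor markers, and as many were markers of another class, such as the monocyte/macrophage markers S100A8 and S100A9. Clusters 19 and 24 also had CCL2, CCL3, PRG2 or CLC among their leading genes. The remaining marker lists, for plasmacytoid dendritic, T, NK, erythroid, plasma, stem or progenitor and stromal cells and for megakaryocytes, named no cluster here. When each library was clustered alone 1.56% (1.301 to 1.85) of the fresh cells were plasmacytoid dendritic cell-like, and with the stricter cell filter 1.24% (1.01 to 1.51). A cluster drawn almost wholly from 1 library, as most of these were, may stand for that library and not for a cell type. Clusters 3, 7, 16, 18, 19, 22 and 24 drew cells from both cultures. The DC and macrophage cultures had 1305 and 156 cells in cluster 3, 542 and 790 in cluster 7 and 312 and 149 in cluster 16. The names rest on markers that themselves differ between the libraries.

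Among the unnamed clusters, cluster 4 (JAML, GZMB, SERPINF1) held 13.1% (12.5 to 13.7) of the DC culture. Its closest marker list was dendritic cell, with 9 markers detected. GZMB and SERPINF1, markers of another class among its leading genes, kept it unnamed. Cluster 7, with MAL, VCAN and CD34 among its leading genes, held 4.92% (4.52 to 5.34) of the DC culture, 14.2% (13.3 to 15.2) of the macrophage culture and 0.0491% (0.0134 to 0.126) of the fresh cells. The closest list of cluster 7 was B-lymphoid, with 3 markers detected. It stayed unnamed because VCAN and CD34 are markers of other classes and no B-lymphoid marker was among its leading genes. The B-lymphoid-like and myeloid-like shares leave out clusters 4 and 7 by this rule on leading genes. Cluster 26 (IRF8, CPVL, LYZ) held 0.663% (0.498 to 0.864) of the fresh cells. Clusters 22, 25 and 27 had few UMIs and no marker of their closest class among the leading genes, and a rule on UMIs that was set after the data were seen kept them out of the myeloid-like class. Cluster 22 held 1.27% (1.07 to 1.498) of the DC culture and 1.87% (1.53 to 2.26) of the macrophage culture, cluster 25 held 2.77% (2.36 to 3.24) of the macrophage culture, and cluster 27 held 0.463% (0.345 to 0.608) of the DC culture. The doublet caller marked 12.1% of the DC culture and 2.95% of the macrophage culture. It marked 3 of 8146 fresh cells (0.0368%), so doublets could not be judged in that library, and called doublets were kept in every library. In cluster 12, 93.3% of the cells were called doublets, and their median was 38245 UMIs.

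Scaling moved all ratios against the fresh library together. Median-of-ratios factors added 0.44 and TMM factors 0.47 to each log2 ratio of the DC culture over the fresh blasts, and totals without mitochondrial and ribosomal protein genes shifted them by -0.24. The same shifts were 0.44, 0.42 and -0.23 for the macrophage culture over the fresh blasts, and -0.01, -0.05 and 0.01 between the cultures. The median log2 ratio over all genes with at least 5 CPM in either library was -0.21, -0.29 and -0.07 for the same comparisons. Single genes change direction with the scaling if their log2 ratio to the fresh library is negative and closer to 0 than the largest positive shift, or positive and closer to 0 than the negative one. The median of each gene list was set among the medians of 10000 random lists of the same size, matched on mean expression, and its percentile describes these libraries.

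The comparison of the DC culture with the fresh blasts asked what set the cells apart after 7 days with IL-4 and GM-CSF. Genes of B-cell precursors were far lower in the DC culture, and genes of dendritic cells, of the IL-4 response, of chemokines and of the interferon response were far higher. VPREB1 (ENSG00000169575, chromosome 22, 22244675 to 22245515), part of the surrogate light chain of the pre-B-cell receptor, was at 0.179 (0.129 to 0.242) CPM in the DC culture and 429 CPM in the fresh blasts, 2396-fold lower. CCL17 (ENSG00000102970, chromosome 16, 57404767 to 57416062), a chemokine of dendritic cells that attracts T cells, was at 7302 CPM against 3.87 (3.51 to 4.25), 1888-fold higher. Of 3453 genes with at least 50 CPM in the higher library, 291 were at least 4-fold higher in the DC culture and 224 at least 4-fold lower.

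The B-cell precursor identity list was lower throughout. Of its 26 measured members 25 were at least 2-fold lower and 0 higher, with a median log2 ratio of -4.15, below all matched random lists. DNTT, the template-independent polymerase of receptor rearrangement, was at 23.6 CPM against 2103. MME, the CD10 antigen of B-cell precursors, was 155-fold lower, and the transcription factor SOX4 7.198-fold lower. LEF1, a transcription factor of early lymphocytes, and POU4F1 were lower by 95.8-fold and 57.1-fold. KCNK12, ARPP21, C1QTNF4, CEACAM6 and RAB37 completed the 10 lowest ratios, from -7.98 for KCNK12 to -5.19 for RAB37 on the log2 scale.

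Dendritic cell genes had a median log2 ratio of 6.17, above all matched random lists, and 17 of 18 measured members were at least 2-fold higher. CCL22, a chemokine that binds the same receptor as CCL17, was at 1561 CPM against 0.217 (0.139 to 0.323). FSCN1, the actin-bundling protein of mature dendritic cells, was 10.3-fold higher, and CCR7, the receptor that guides dendritic cells to lymph nodes, 43.9-fold higher. CD1C, which presents lipid antigens, was at 250.1 CPM against 2.11 (1.85 to 2.403). CD207 (ENSG00000116031, chromosome 2, 70830214 to 70835822), the langerin of Langerhans cells, was at 187 CPM and had 1 count in the fresh library. PLAAT3, a phospholipase, was at 223 CPM against 0.0723 (0.0312 to 0.142).

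Macrophage genes were higher as well, at a median of 5.19 with 14 of 15 members at least 2-fold higher, above all matched random lists. The elastase gene MMP12 (ENSG00000262406, chromosome 11, 102862736 to 102875034), which had no count in the fresh library, was at 829 CPM, at least 30573-fold higher against a floor of 3 counts in the fresh library. The complement genes C1QB, C1QC and C1QA, also without a fresh count, were at 295, 187 and 169 CPM. LYZ, lysozyme, was 16.9-fold higher, while the scavenger receptor gene MSR1 was lower at 2.49 (2.29 to 2.702) CPM against 7.63 (7.12 to 8.16). Among myeloid transcription factors 7 of 13 were at least 2-fold higher and 1 lower, with a median of 1.23 at the 99.95 percentile. IRF4, a factor of dendritic cells and plasma cells, was 59.6-fold higher, BATF3 19.6-fold and SPI1, the PU.1 factor of myeloid cells, 4.01-fold. ID2 was 2.61-fold and EGR2 83.7-fold higher, and ZEB2 was 2.01-fold lower. S100A8, at 254 CPM with a log2 ratio of 13.19 (11.64 to 15.47), and CLC, at 176 CPM with no fresh count, were among the 10 highest ratios. Both lead clusters of the granulocyte precursor-like and mast cell, basophil or eosinophil-like cells described above.

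Chemokines and IL-4 targets formed the next groups. In the cytokine and chemokine list 12 of 17 members were at least 2-fold higher and 1 lower, with a median of 4.91, above all matched random lists. CCL2 was 29.4-fold, CXCL10 285-fold, CCL5 29.98-fold and CXCL8 37.1-fold higher. IL12B, a subunit of interleukin-12, was at 4.54 CPM against 23.03. The IL-4 response list, which shares CCL17, CCL22 and CCL13 with other lists, had a median of 7.03, above all matched random lists, and 13 of 15 members were at least 2-fold higher. CCL13 was at 465 CPM with a log2 ratio of 14.07 (12.52 to 16.34), and the protease CTSC was 12.9-fold higher. F13A1, coagulation factor XIII, had a log2 ratio of -0.08, whose direction depends on the scaling.

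Genes of antigen presentation went both ways. For MHC class II presentation the median was -0.63, at the 0.9 percentile, with 2 of 14 members at least 2-fold higher and 5 lower. HLA-DRA, a class II chain, was at 5993 CPM in the DC culture and 6097 in the fresh blasts, and HLA-DRB1 at 3408 against 3524, both within the range where the scaling sets the direction. CD74, the invariant chain, and HLA-DPA1 each had a log2 ratio of 0.36. IFI30, a lysosomal thiol reductase that prepares antigens, was 15.9-fold higher, and HLA-DOA was 4.18-fold lower. Class I presentation had a median of 0.38 at the 83.27 percentile and 3 of 16 members at least 2-fold higher. B2M was 1.48-fold and the chaperone gene CALR 3.11-fold higher, and HLA-B and HLA-C had log2 ratios of -0.25 and -0.22, which turn with the scaling. HLA genes are polymorphic and alike, so their counts rest on 1 reference sequence. Costimulation and checkpoint ligands had a median of 1.16, above all matched random lists, with 8 of 15 members at least 2-fold higher and 3 lower. CD80 and CD86, the ligands of CD28 on T cells, were at 67.1 and 141 CPM against 0.145 (0.0826 to 0.235) and 2.801 (2.498 to 3.13). CD40 was 2.24-fold and LGALS9 2.32-fold higher, CD58 was 1.55-fold lower, and TNFSF4, the OX40 ligand, was 8.04-fold lower.

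Interferon response genes were higher without exception among 16 members, with a median of 3.62, above all matched random lists. ISG15 (ENSG00000187608, chromosome 1, 1001138 to 1014540), a ubiquitin-like protein induced by interferon, was at 2916 CPM against 75.2. IFI6 was 28.8-fold and MX1 17.98-fold higher. Phagocytosis and lysosome genes had a median of 1.53, above all matched random lists, and 15 of 24 were at least 2-fold higher. CTSZ was 34.7-fold, TYROBP 28.5-fold, FCER1G 46.9-fold, GRN 5.02-fold and CYBA 2.01-fold higher, while NCF4 was 2.08-fold lower. Lipid handling and cholesterol genes had a median of 0.90 at the 99.96 percentile, with 7 of 15 at least 2-fold higher and 2 lower. FABP5 was 5.22-fold, CD36 39.96-fold, LIPA 3.64-fold and INSIG1 1.67-fold higher, and PLIN2 was 3.03-fold lower.

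For cell cycle genes the median was 0.65 at the 99.91 percentile, and 4 of 20 members were at least 2-fold higher. AURKA was 2.396-fold, TYMS 1.798-fold and MKI67 1.42-fold higher. TOP2A was 1.42-fold lower, and CENPF, at -0.25 on the log2 scale, turns with the scaling. Apoptosis and p53 target genes had a median of -0.47 at the 5.92 percentile, with 3 of 14 members at least 2-fold higher and 5 lower. BCL2A1, an inhibitor of apoptosis, was 19.7-fold, CDKN1A 4.12-fold and PMAIP1 1.65-fold higher, and BBC3 was 5.102-fold and BAX 1.44-fold lower. Stress and dissociation genes had a median of 0.71 at the 98.99 percentile, and 6 of 13 were at least 2-fold higher. ATF3 was 7.91-fold, IER3 3.27-fold and JUNB 2.005-fold higher, IER2 was 1.51-fold lower, and JUND, at -0.33, turns with the scaling. Receptors of the cytokines in the cultures were also read. CSF2RA and CSF2RB, the chains of the GM-CSF receptor, were 37.9-fold and 19.1-fold higher, IL4R 2.17-fold, CSF1R 5.62-fold and IL3RA 1.44-fold.

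Scaling changed the balance of these counts. The 56.5% of the at least 4-fold differences that were higher in the DC culture became 75.9% with median-of-ratios factors (418 higher and 133 lower), 76.9% with TMM factors (427 higher and 128 lower) and 42.6% with totals without mitochondrial and ribosomal protein genes (282 higher and 380 lower). With genes of at least 10 CPM it was 47.03% (571 higher and 643 lower).

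The comparison of the macrophage culture with the fresh blasts asked the same of M-CSF, IL-3 and GM-CSF. B-cell precursor genes were again far lower, and macrophage, cytokine and chemokine, lysosome and interferon response genes were far higher. CD14 (ENSG00000170458, chromosome 5, 140631728 to 140633701), the lipopolysaccharide co-receptor of monocytes and macrophages, was at 299 CPM in the macrophage culture and 0.154 (0.0895 to 0.246) CPM in the fresh blasts. MMP12 was at 2098 CPM and had no fresh count, at least 77384-fold higher. VPREB1 was 455-fold lower, at 0.943 (0.8001 to 1.104) CPM. Of 3489 genes compared, 379 were at least 4-fold higher and 183 at least 4-fold lower in the macrophage culture.

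In the macrophage list all 23 measured members were at least 2-fold higher, with a median of 6.72, above all matched random lists. C1QA, C1QB and C1QC, without a fresh count, were at 692, 461 and 358 CPM, and at least 25532-fold, 17019.7-fold and 13214-fold higher. SPP1, osteopontin, was at 1159.6 CPM against 0.994 (0.817 to 1.198), and LYZ was 25.04-fold higher. CD163, the haemoglobin scavenger receptor, was at 71.8 CPM against 0.0723 (0.0312 to 0.142), and the mannose receptor gene MRC1 was 4.802-fold higher. Among myeloid transcription factors 12 of 17 were at least 2-fold higher and 1 lower, at a median of 2.05, above all matched random lists. CEBPB was 9.89-fold, SPI1 4.15-fold, ID2 2.75-fold and ZEB2 1.61-fold higher, MITF was at 14.998 CPM with 1 fresh count, and CEBPA was 2.62-fold lower. The dendritic cell list was higher too, at a median of 5.29, above all matched random lists, with 14 of 16 members at least 2-fold higher and 1 lower. CCL17 was 286-fold, CCL22 3087-fold, CCR7 42.4-fold and FSCN1 6.29-fold higher, and the FLT3 receptor gene was 2.25-fold lower. S100A8 was at 571 CPM with a log2 ratio of 14.36 (12.81 to 16.64). The granulocyte precursor-like share of this library was 5.58% in the main clustering and as low as 1.303% in other settings.

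The B-cell precursor identity list had 24 of 26 members at least 2-fold lower and 0 higher, with a median of -4.41, below all matched random lists. CD79A and CD79B, the signalling chains of the B-cell receptor, were 123-fold and 30.1-fold lower. DNTT was at 62.5 CPM, 33.7-fold lower, MME 43.1-fold and SOX4 9.61-fold lower. KCNK12, JCHAIN, C1QTNF4, ARPP21 and CEACAM6, the other genes of the 10 lowest ratios, lay between -7.88 and -5.31 on the log2 scale. CD72 was 1.67-fold higher.

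Cytokines and chemokines had a median of 6.93, above all matched random lists, with 16 of 20 members at least 2-fold higher and 1 lower. CCL2 was at 2726 CPM, 98.03-fold higher, CXCL8 151-fold, CCL5 83.7-fold and IL1B, interleukin-1 beta, 22.4-fold higher. CCL8 was at 1699 CPM with 2 fresh counts, CCL4 at 1056 with 5, and CCL18 at 209.9 with none. CCL7 had a log2 ratio of 13.69 (12.15 to 15.97), and IL12B was 2.49-fold lower. CCL4 has a near-identical copy, so its count is uncertain. In the phagocytosis and lysosome list 21 of 25 members were at least 2-fold higher and 1 lower, at a median of 2.36, above all matched random lists. The lysosomal proteases CTSL and CTSB were at 471 and 1351 CPM against 0.0542 (0.0199 to 0.118) and 46.8. CTSZ was 39.3-fold, TYROBP 34.9-fold and CYBA 1.896-fold higher, and NCF4 was 2.83-fold lower. The IL-4 response list, in a culture whose label names no IL-4, had a median of 6.43, above all matched random lists, with 11 of 13 members at least 2-fold higher. IL4I1 was 86.4-fold and CTSC 14.4-fold higher, CCL13 had a log2 ratio of 12.80 (11.26 to 15.08), and SOCS1, at -0.01, turns with the scaling. Lipid handling and cholesterol genes had a median of 1.24, above all matched random lists, and 9 of 17 were at least 2-fold higher. APOE was at 204 CPM against 0.741 (0.589 to 0.9196), FABP5 was 4.38-fold and LIPA 4.03-fold higher, and PLIN2 was 1.71-fold lower.

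All 16 interferon response genes were at least 2-fold higher, with a median of 3.99, above all matched random lists. ISG15 was at 3628 CPM, 48.2-fold higher, RSAD2 76.4-fold, IFI6 29.2-fold and MX1 13.2-fold higher. For MHC class II presentation the median was -0.46 at the 7.81 percentile, with 2 of 14 members at least 2-fold higher and 5 lower. CIITA (ENSG00000179583, chromosome 16, 10866222 to 10943021), the transactivator of class II genes, was 3.96-fold lower, IFI30 was 18.7-fold higher, and HLA-DPB1 was 1.36-fold lower. HLA-DRA, HLA-DRB1 and CD74 had log2 ratios of -0.14, -0.36 and 0.04, which turn with the scaling. Class I presentation had a median of 0.14 at the 77.97 percentile that turned with the scaling, from -0.09 to 0.58, and 2 of 16 members were at least 2-fold higher. TAP1, a peptide transporter, was 2.503-fold higher, while B2M, HLA-B and HLA-C, at 0.22, -0.26 and -0.19, turn with the scaling. Costimulation and checkpoint ligands had a median of 1.40 at the 99.99 percentile, with 9 of 15 members at least 2-fold higher and 3 lower. CD80 was at 76.4 and CD86 at 158 CPM, the adhesion ligand ICAM1 was 33.2-fold, CD40 2.64-fold, LGALS9 2.19-fold and CD48 1.78-fold higher, and CD70 was 4.73-fold lower.

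Cell cycle genes had a median of -0.42 at the 23.03 percentile, from -0.65 to 0.01 across the scalings, with 4 of 20 members at least 2-fold lower and 1 higher. TOP2A was 3.06-fold, CENPF 2.48-fold and MKI67 1.88-fold lower, PCNA turned with the scaling from -0.29, and MCM5 was 2.01-fold higher. Apoptosis and p53 target genes had a median of -0.56 at the 4.91 percentile, with 3 of 14 members at least 2-fold higher and 3 lower. BCL2A1 was 30.4-fold, CDKN1A 4.099-fold and MCL1 3.72-fold higher, and BBC3 was 5.33-fold and BAX 1.798-fold lower. Stress and dissociation genes had a median of 1.81, above all matched random lists, and 10 of 13 were at least 2-fold higher. EGR1 was 22.9-fold, IER3 6.55-fold, JUNB 3.45-fold and FOS 2.47-fold higher, and JUND 1.47-fold lower. CSF1R, the M-CSF receptor, was 21.8-fold, CSF2RA 32.3-fold, CSF2RB 19.8-fold, IL4R 3.68-fold and IL3RA, the IL-3 receptor chain, 1.72-fold higher.

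With another scaling the 67.4% of the at least 4-fold differences that were higher in the macrophage culture became 84.01% (median-of-ratios, 515 higher and 98 lower), 83.7% (TMM, 503 higher and 98 lower) and 54.4% (totals without mitochondrial and ribosomal protein genes, 384 higher and 322 lower). With genes of at least 10 CPM it was 57.9% (747 higher and 543 lower).

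The comparison between the cultures asked how the macrophage conditions differed from the DC conditions. Macrophage, cytokine and lysosome genes were higher in the macrophage culture, and dendritic cell and cell cycle genes were higher in the DC culture. CD14 was at 299 CPM in the macrophage culture and 1.301 (1.16 to 1.46) CPM in the DC culture, 229-fold apart, and CD207 was at 3.63 (3.34 to 3.93) against 187 CPM. Of 3123 genes compared, 98 were at least 4-fold higher and 24 at least 4-fold lower in the macrophage culture.

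Of the 23 macrophage genes 16 were at least 2-fold higher in the macrophage culture and 0 lower, at a median of 2.19, above all matched random lists. CD163 (ENSG00000177575, chromosome 12, 7470813 to 7503893) was at 71.8 against 0.0683 (0.03902 to 0.111) CPM, SPP1 was 32.05-fold, C1QA 4.0997-fold, GPNMB 64.7-fold and LYZ 1.48-fold higher, and CD36 was 1.66-fold lower. Myeloid transcription factors had a median of 0.61 at the 99.99 percentile, with 7 of 17 at least 2-fold higher and 2 lower. CEBPB was 9.02-fold and ZEB2 3.24-fold higher, BATF3 was 6.202-fold lower, and SPI1 and ID2 were within 1.05-fold. Cytokines and chemokines had a median of 1.61, above all matched random lists, with 13 of 20 at least 2-fold higher and 1 lower. CXCL5 was 171-fold, IL1B 15.4-fold, CXCL8 4.08-fold and CCL2 3.34-fold higher, and CCL13 was 2.396-fold lower. CCL7, CXCL3 and CCL8 were 94.04-fold, 73.96-fold and 70.8-fold higher. The phagocytosis and lysosome median was 0.74, above all matched random lists, and 10 of 25 genes were at least 2-fold higher. CTSL was 189.6-fold and CTSB 8.29-fold higher, and the matrix metalloproteinase gene MMP14 was 31.9-fold higher. The metallothionein gene MT1H, one of a family of near-identical copies, was at 197 against 4.63 CPM.

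Dendritic cell genes were lower in the macrophage culture, at a median of -1.59, below all matched random lists, with 10 of 18 members at least 2-fold lower and 0 higher. CD207 was 51.5-fold, CCL17 6.61-fold and CCL22 2.33-fold lower, CD1B 12.2-fold, CD1E 8.02-fold and CD1C 3.89-fold lower. CCR7 had a log2 ratio of -0.05, and CLEC4A was 1.91-fold higher. PTP4A3, RAMP1, PLAAT3, HOMER2 and PPP1R14A, also among the 10 lowest ratios, lay between -3.78 and -3.13 on the log2 scale. The IL-4 response list had a median of -0.60, below all matched random lists, with 6 of 15 members at least 2-fold lower and 3 higher. ALOX15, a lipoxygenase induced by IL-4, was at 0.135 (0.0844 to 0.204) against 46.3 CPM, and the transglutaminase gene TGM2 was 12.6-fold higher. Cell cycle genes had a median of -1.09, below all matched random lists, with 15 of 20 at least 2-fold lower. BUB1 was 2.79-fold, MKI67 2.66-fold, TYMS 2.46-fold and CENPF 2.08-fold lower. Cells of the cycling cluster 3 made up 11.8% (11.2 to 12.5) of the DC culture and 2.81% (2.39 to 3.28) of the macrophage culture.

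The other lists lay closer together. B-cell precursor identity had a median of 0.04 at the 58.29 percentile, from -0.01 to 0.05 across the scalings, so it had no fixed direction, with 5 of 16 members at least 2-fold higher and 3 lower. CD72 was 5.45-fold and DNTT 2.65-fold higher, and MS4A1, the CD20 antigen, was at 0.759 (0.632 to 0.905) against 8.86 CPM. Cluster 7, whose cells carried DNTT, made up 14.2% of the macrophage culture and 4.92% of the DC culture. MHC class II presentation had a median of -0.01 with 1 of 14 members at least 2-fold higher, the protease CTSS at 2.42-fold, and lay at the 83.93 percentile. Class I presentation had a median of -0.20 at the 34.69 percentile, with no member 2-fold apart. Costimulation and checkpoint ligands had a median of 0.16 at the 97.23 percentile, with TNFSF9 2.18-fold and ICAM1 2.14-fold higher. Interferon response genes had a median of 0.25 at the 99.82 percentile, and RSAD2 was 3.46-fold higher and IRF7 1.46-fold lower. Lipid handling and cholesterol had a median of 0.14 at the 94.88 percentile, APOE being 47.8-fold higher and HMGCS1, of sterol synthesis, 1.94-fold lower. Apoptosis and p53 target genes had a median of 0.23 at the 98 percentile, with GADD45A 2.22-fold lower. Stress and dissociation genes were higher in the macrophage culture, at a median of 1.01, above all matched random lists, with 8 of 13 at least 2-fold higher, among them EGR1 at 3.56-fold and FOS at 2.02-fold. CSF1R was 3.88-fold higher in the macrophage culture, IL4R 1.69-fold and IL3RA 1.197-fold. With genes of at least 10 CPM the counts were 242 higher and 63 lower.

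**Figure D2:**
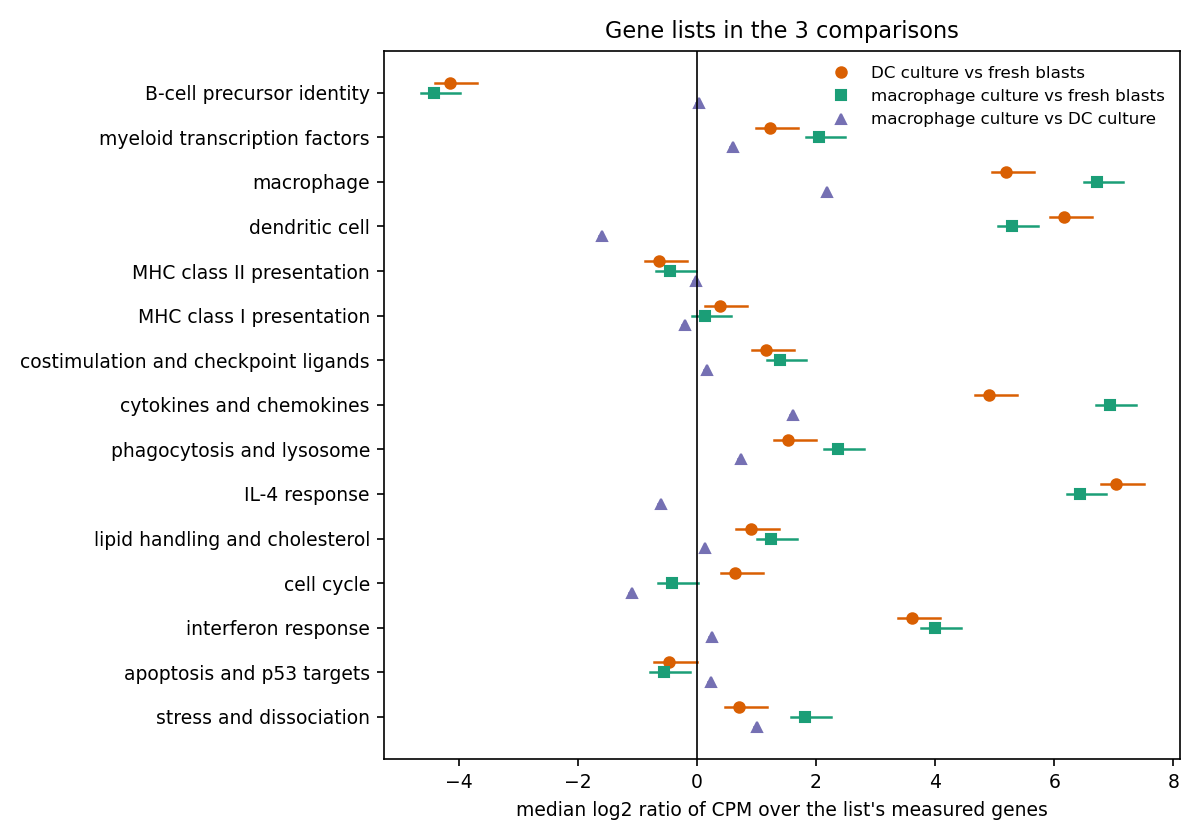
Median log2 ratio of CPM (horizontal axis) of each of the 15 gene lists in the 3 comparisons, 1 library per group, with horizontal lines for the range over the 4 scalings. Class I presentation and cell cycle of the macrophage culture over the fresh blasts, and B-cell precursor identity between the cultures, cross 0 with the scaling.

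**Figure D3:**
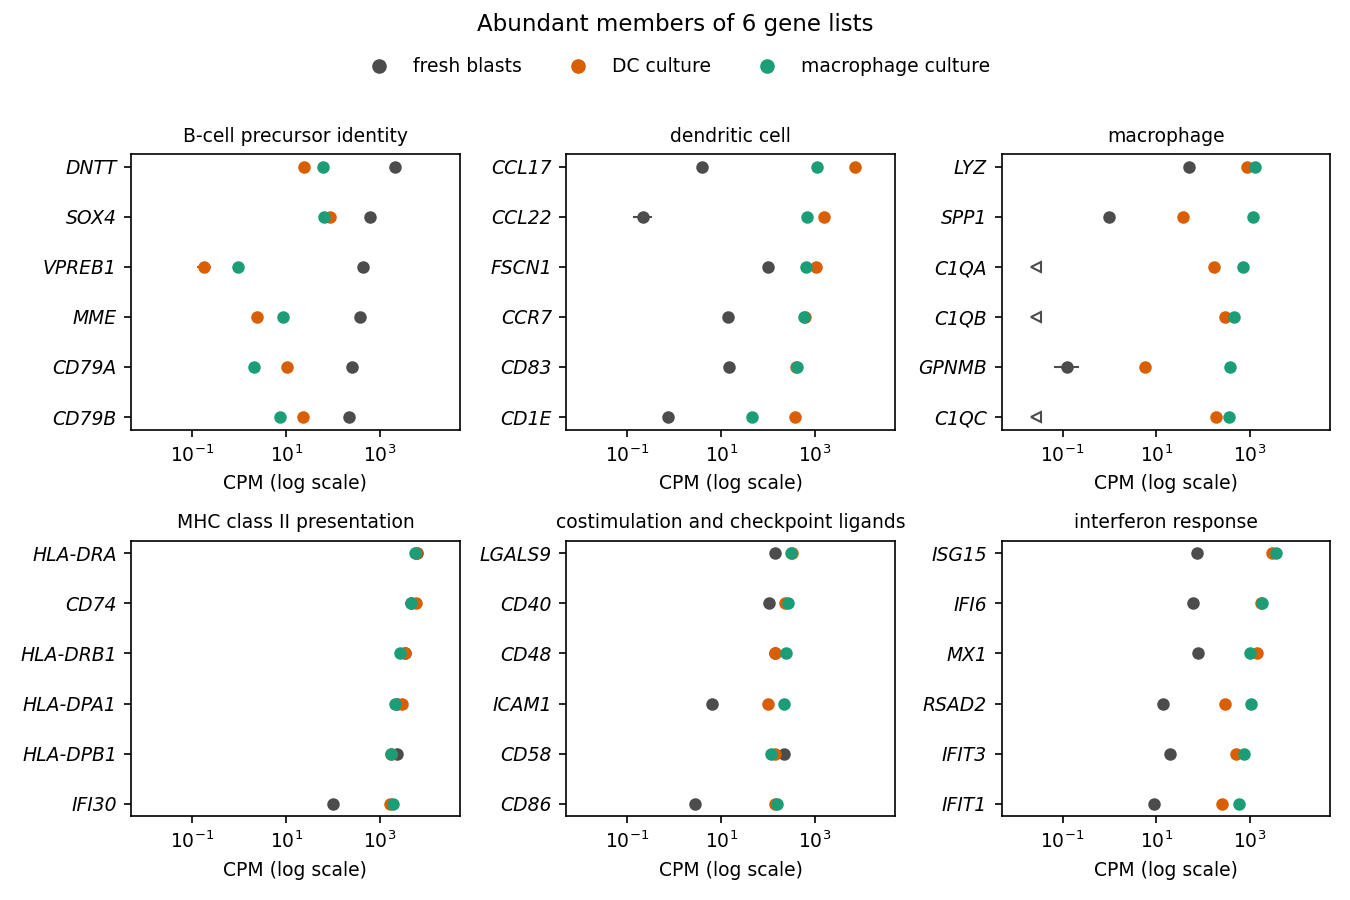
CPM (horizontal axis, log scale) of 6 abundant members of each of 6 gene lists in the fresh blasts, the DC culture and the macrophage culture, 1 library each, with lines for exact 95% intervals and open triangles at the floor for fewer than 3 counts. VPREB1 was at 429 CPM in the fresh blasts, CCL17 at 7302 CPM in the DC culture and SPP1 at 1159.6 CPM in the macrophage culture.

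Within the myeloid-like cells most lists had medians near those of the whole libraries. Here 3949 cells of the macrophage culture, nearly all from clusters 1, 3, 6 and 14, were compared with 7916 cells of the DC culture, nearly all from clusters 2, 3, 5, 8, 12, 13 and 23. Macrophage genes had a median of 2.38, with 17 of 23 at least 2-fold higher. CD14 was at 314 against 0.575 (0.471 to 0.695) CPM and CD163 at 81.7 against 0.0434 (0.0187 to 0.0855). Dendritic cell genes had a median of -1.62 with 10 of 18 at least 2-fold lower, CD207 being at 4.35 (3.996 to 4.72) against 233 CPM. Cell cycle genes had a median of -1.36 with 18 of 20 at least 2-fold lower. Cytokines and chemokines had a median of 1.69, stress and dissociation 1.17, phagocytosis and lysosome 0.92, myeloid transcription factors 0.76 and B-cell precursor identity -0.61. The last of these lay at the 0.45 percentile of matched random lists, against the 58.29 percentile in the whole libraries. IL-4 response, at -0.32 and the 6.18 percentile, was closer to 0 than in the whole libraries, where it lay below all matched random lists. Interferon response, at 0.31, apoptosis and p53 targets, at 0.26, and lipid handling and cholesterol, at 0.16, were also near 0. Class I and class II presentation and costimulation and checkpoint ligands were at -0.19, -0.14 and 0.10. Of 3133 genes compared within this class 127 were at least 4-fold higher in the macrophage culture and 30 at least 4-fold lower.

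Within the B-lymphoid-like cells, 351 cells of the DC culture, nearly all from cluster 18, were compared with 8084 fresh cells, nearly all from the clusters named above. Cluster 18 held 2 fresh cells, so the class does not hold the kind of B-lymphoid cell fixed. The class also rests on the clustering. The DC culture held 10 such cells at resolution 0.5, 10 with 1000 variable genes and 15 components, and 15 without called doublets, under the minimum of 100. B-cell precursor identity had a median of -1.86, with 18 of 27 members at least 2-fold lower and 3 higher. VPREB1 was at 2.74 (1.59 to 4.38) against 435 CPM, DNTT at 108 (100.3 to 117) against 2130.2 and MME at 14.97 (12.1 to 18.3) against 373. In the other direction MS4A1, an antigen of mature B cells, was at 210.04 against 21.3 CPM, and TCL1A at 18.5 (15.3 to 22.2) against 6.28 (5.82 to 6.77). All 16 interferon response genes were at least 2-fold higher, at a median of 2.79, with ISG15 at 1294 against 74.3 CPM. Class II presentation had a median of -1.05 with 7 of 14 at least 2-fold lower, CIITA being at 77.6 (70.8 to 84.8) against 258 CPM. Stress and dissociation genes, at -0.98, and apoptosis and p53 targets, at -0.94, were lower. Dendritic cell genes, at 4.46, IL-4 response, at 4.39, macrophage, at 1.77, and cytokines and chemokines, at 1.11, were higher. CCL17 in these cells was at 2.74% of its level in myeloid-like cells of the same culture, and RNA free in the droplets, low expression and mixed droplets were not told apart. MAOA, an IL-4 target that had no count in fresh B-lymphoid-like cells, was at 101 (93.2 to 109) CPM, against 72.8 CPM in the myeloid-like cells of the DC culture. The medians were 0.35 for costimulation and checkpoint ligands, 0.43 for lipid handling and cholesterol, 0.34 for phagocytosis and lysosome, 0.11 for class I presentation, -0.30 for myeloid transcription factors and -0.31 for cell cycle. Of 3264 genes compared 89 were at least 4-fold higher in the DC culture and 120 at least 4-fold lower. The macrophage culture held 95 B-lymphoid-like cells, under the minimum of 100, and was not compared within this class.

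Key surface molecules were also read per cell, with each cell thinned to 2000 UMIs. Cells below that depth were left out, 57 of the fresh blasts, 126 of the DC culture and 61 of the macrophage culture, and the median depth of the others before thinning was 11696, 18438 and 29254 UMIs. Mast cell, basophil or eosinophil-like cells, with median depths of 4483 and 5219 UMIs in the cultures, served as background. CD86 was found in 0.371% (0.2504 to 0.529) of the fresh cells, 23.4% (22.6 to 24.2) of the DC culture and 21.96% (20.9 to 23.1) of the macrophage culture, beside 2.47% and 3.01% background in the cultures. CD80 was found in 0 of 8089 fresh cells, where 3 cells with a UMI at that depth would be 0.0371%, in 13.3% (12.7 to 13.97) of the DC culture and in 13.03% (12.1 to 13.9) of the macrophage culture, with 1.23% and 2.26% background. Without thinning the shares of CD86 were 2.53%, 69.1% and 68.4%, and those of CD80 0.123%, 54.4% and 57.5%. CD40, found in 17.9% (17.1 to 18.8) of the fresh cells, was found in 33.2% (32.3 to 34.1) and 36.01% (34.7 to 37.3) of the DC and macrophage cultures, with 3.704% and 3.01% background and 59.7%, 79.98% and 86.9% without thinning.

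CD1C was found in 0.198% (0.113 to 0.321) of the fresh cells, 25.4% (24.6 to 26.2) of the DC culture and 8.77% (8.04 to 9.55) of the macrophage culture, with 3.29% and 0.752% background and unthinned shares of 0.773%, 56.7% and 32.2%. CD14 was found in 21.98% (20.9 to 23.1) of the macrophage culture, 49.1% without thinning, against a background of 4.51%. In the DC culture its share was 0.285% (0.193 to 0.404), 1.77% without thinning, and background could not be told from expression because it rests on 1 of 243 cells, 0.412% (0.0104 to 2.27). Of the 31 cells with a UMI 15 were granulocyte precursor-like. The fresh cells had 0.0618% (0.0201 to 0.144), 0.196% without thinning. CD163 was found in 10.2% (9.37 to 10.98) of the macrophage culture, 31.7% without thinning, with 0 of 133 background cells. Its shares of 0.0247% in the fresh blasts and 0.00918% in the DC culture, 0.0982% and 0.109% without thinning, stand on 2 cells and 1 cell. MRC1 was found in 7.02% (6.47 to 7.601), 12.2% (11.5 to 12.8) and 21.6% (20.6 to 22.7) of the fresh, DC and macrophage libraries, with 2.06% and 0.752% background and 28.4%, 47.4% and 68.7% without thinning. CSF1R was found in 0.396% (0.271 to 0.558), 3.63% (3.28 to 3.99) and 11.9% (11.1 to 12.8), with 0 of 243 and 1.504% of background cells and 3.41%, 23.5% and 50.3% without thinning.

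For ITGAM, which mast cells and granulocytes also use, the B-lymphoid-like cells of the cultures served as background, with median depths of 16232 and 21084 UMIs. ITGAM, the CD11b integrin, was found in 0.6799% (0.513 to 0.884), 2.59% (2.299 to 2.905) and 3.51% (3.04 to 4.03) of the fresh, DC and macrophage libraries, with 0.289% and 0 of 94 background cells and 3.66%, 15.2% and 25.6% without thinning. SPI1 was found in 16.3% (15.5 to 17.1), 51.9% (51.003 to 52.9) and 49.4% (48.1 to 50.7), beside 15.9%, 20.5% and 15.96% of their B-lymphoid-like cells, which are no background because fresh B-lymphoid-like cells carried it too, and 57.7%, 94.8% and 93.1% without thinning. Of the 10 molecules 9 were found in a larger share of the DC culture than of the fresh cells, and 10 in a larger share of the macrophage culture.

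**Figure D4:**
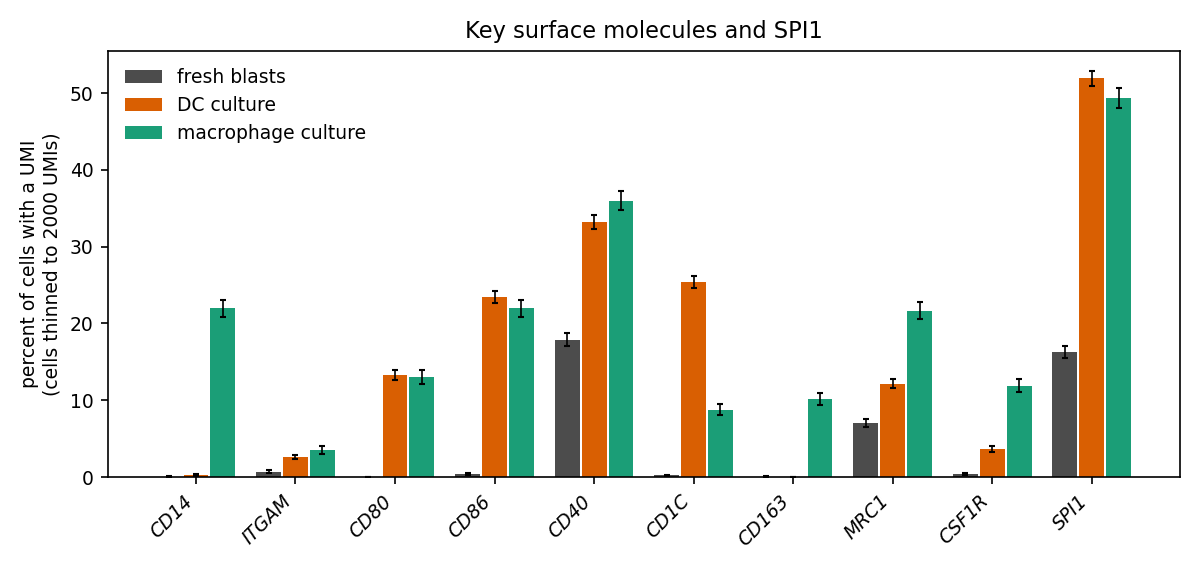
Share of cells with at least 1 UMI (percent) of each of 10 key molecules after thinning to 2000 UMIs, in the fresh blasts, the DC culture and the macrophage culture, 1 library each, with error bars for exact 95% intervals. CD14 and CD163 stand out in the macrophage culture at 21.98% and 10.2%, and CD1C in the DC culture at 25.4%.

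To look for cells between the lymphoid and myeloid states, cells with both kinds of transcripts were counted after thinning to 2000 UMIs. These had UMIs of at least 2 B-lymphoid and at least 2 myeloid markers. They were 26 of 8089 fresh cells, 0.321% (0.2101 to 0.471), 4 of 10892 cells of the DC culture, 0.0367% (0.01001 to 0.094002), and 8 of 5496 of the macrophage culture, 0.146% (0.0629 to 0.287). These shares depend on depth, and were 0.0123%, 0% and 0% at 1000 UMIs. None of the myeloid markers used is in the dendritic cell list. At least 2 of them were found in 17.5% of the myeloid-like cells of the DC culture and 55.3% of those of the macrophage culture. Mixed cells were therefore more easily missed in the DC culture, and the shares of the libraries are not on an equal footing. At least 2 B-lymphoid markers were found in 73.9% of the fresh cells, 1.91% of the DC culture and 2.75% of the macrophage culture. MRC1, also a myeloid marker here, was found in 7.02% of the fresh cells. The higher fresh share therefore does not show more cells between the states. All fresh cells with both kinds were B-lymphoid-like, 0.324% (0.212 to 0.474) of that class, where 0.473% would be expected if the markers fell on its cells independently. Of the myeloid-like cells 1 of 7902 in the DC culture had both kinds, 0.0127% (0.0003204 to 0.0705), against 0.0885% by the same measure, and 4 of 3941 in the macrophage culture, 0.101% (0.0277 to 0.2597), against 0.1402%. B-lymphoid-like cells of the DC culture had 1 of 346, 0.289% (0.00732 to 1.5997), against 0.179%. The doublet caller marked 1 of these cells in the DC culture and 2 in the macrophage culture.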

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

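All tests in this part were chosen only after the result was seen.

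Cell types that no comparison used formed clusters in the cultures only. Mast cell, basophil or eosinophil-like cells made up 2.83% of the DC culture and 2.68% of the macrophage culture, and granulocyte precursor-like cells 2.39% and 5.58%. In other settings the second class was as low as 1.38% and 1.303%. All these shares lie above 0.0368%, the limit of 3 cells set for the 0 of 8146 fresh cells. The tables argue against a myeloid-like cell and another cell in 1 droplet for the first class. Its median UMIs were 0.193 and 0.15 times those of myeloid-like cells in the DC and macrophage cultures. For the second class, at 0.488 and 0.742 times, the medians cannot decide. It joins clusters 19 and 24 with medians of 23756.5 and 7425 UMIs. After thinning, at least 2 myeloid markers were found in 51.6% and 73.7% of its cells, against 17.5% and 55.3% of myeloid-like cells. Droplets with 2 smaller cells were not tested. Outgrowth of other marrow cells too few to form a cluster may account for the first class: 4 fresh cells had UMIs of at least 3 of its markers after thinning, where 100 shuffles of the markers over the cells gave 0. For the granulocyte precursor-like class 0 fresh cells did, and since DNTT, CD79A or CD79B UMIs were found in 2.71% (1.098 to 5.51) of its cells in the DC culture and 2.27% (0.919 to 4.63) in the macrophage culture, against 2.85% and 1.98% of myeloid-like cells, outgrowth and an origin from blasts cannot be told apart there, and an origin from blasts under the cytokines stays open for both classes.

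Cell cycle genes had medians of opposite sign against the fresh library, 0.65 in the DC culture and -0.42 in the macrophage culture. The second turned with the scaling and came to 0.01 with median-of-ratios factors, while the median between the cultures, -1.09, below all matched random lists, ran from -1.14 to -1.08 over the scalings. The cause of the difference was not tested.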

How the results depend on the processing

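The alternatives with myeloid-like cells of the cultures alone, and without unnamed clusters and other cell types, were chosen only after the data were seen. No paired analysis was possible because each group holds 1 library and no result comes from a test. No list median and no named gene that was at least 2-fold apart changed direction under any alternative run. Of the values that answer a comparison under an alternative, 99 stayed within 1.5 times a count or within the interval of a share and 59 moved, 29 to higher and 30 to lower values; the cause was not tested, except that a lower expression filter compares more genes. Genes at least 4-fold lower than in the fresh blasts, 224 in the DC culture and 183 in the macrophage culture, came to 133 and 98 with median-of-ratios factors, 128 and 98 with TMM factors, and 380 and 322 with totals without mitochondrial and ribosomal protein genes. With genes of at least 10 CPM 571 were higher and 643 lower in the DC culture than in the fresh blasts, 747 and 543 in the macrophage culture, and 242 and 63 between the cultures. With no expression filter these counts were 1749 and 3690, 2168 and 2845, and 1155 and 319. Between the cultures 5 of 15 list medians were at least 2-fold apart, and 3 when each cell weighed the same. B-lymphoid-like and myeloid-like shares were 99.9% and 0.0491% of the fresh cells at resolution 0.5, 0.0908% and 85.1% of the DC culture and 0.144% and 59.7% of the macrophage culture. At resolution 2 the DC culture had 7.44% and 78.4%. With 1000 variable genes and 15 components the B-lymphoid-like shares were 98.96%, 0.0908% and 0.234% of the fresh, DC and macrophage libraries, and the myeloid-like shares 77.03% and 76.6% of the cultures. Clustered alone, the libraries had 98.4%, 2.78% and 0% B-lymphoid-like cells, and the cultures 77.5% and 68.2% myeloid-like cells. Plasmacytoid dendritic cell-like cells, which formed no class in the clustering of all libraries, were 1.56% (1.301 to 1.85) of the fresh cells there and 1.24% (1.01 to 1.51) with the stricter cell filter. The stricter cell filter gave 98.7% and 0.0502% for the fresh cells, 1.95% and 78.4% for the DC culture and 69.5% myeloid-like cells for the macrophage culture. Without called doublets the B-lymphoid-like shares were 99.9%, 0.155% and 0.1298%, and the myeloid-like shares 62.3% and 67.8%. Named cell by cell from thinned markers, B-lymphoid-like cells were 78.1%, 1.84% and 3.603%, and myeloid-like cells 1.29%, 81.9% and 79.6%. Cells with both kinds of markers were 0.0123%, 0% and 0% after thinning to 1000 UMIs, and 0.0124%, 0% and 0.0182% with at least 3 markers of each kind. Of the named genes' ratios 1120 moved by at least 0.1 on the log2 scale, 716 of them to higher values, and 1553 did not. TMM and median-of-ratios factors each moved 194 to higher values. Totals without mitochondrial and ribosomal protein genes moved 194 to lower values. A scaling adds the same shift to every ratio of a comparison, so these moves say nothing of single genes or lists. Of the list medians 206 moved, 136 of them to higher values, and 289 did not. Shares of cells with a UMI moved in 56 cases, 30 of them higher without thinning and 26 lower at 1000 UMIs. Depth limits the shares of cells with a UMI, and 1 library per group limits every comparison.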

Other observations

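Of the tests in this part, that of free RNA of myeloid-like cells as the source of the interferon response in all classes was chosen beforehand, and the others only after the result was seen.

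Each culture held several kinds of myeloid-like cells. In the macrophage culture cluster 1, led by CCL19, EBI3, CCR7, IDO1 and LAMP3, genes of mature dendritic cells, made up 29.3% (28.1 to 30.5) of the cells. Cluster 6, with CCL8, CTSL, GPNMB and RNASE1, made up 24.7% (23.5 to 25.8), and cluster 14, with SPP1, IL1B, S100A9, MMP9 and CD14, made up 13.7% (12.9 to 14.7). In the DC culture cluster 2, led by the Langerhans cell gene CD207 with CD1B and CCL17, made up 14.6% (13.9 to 15.3), cluster 8, with CCL1, CLEC10A and CD1C, 12.02% (11.4 to 12.6), and cluster 13, with CCL5, CXCL9 and C1QB, 8.804% (8.28 to 9.35). The unnamed cluster 4 of the DC culture had GZMB and SERPINF1, markers of plasmacytoid dendritic cells, among its leading genes beside JAML and PLAC8. Its closest list was nevertheless that of dendritic cells, with 9 markers detected, and not the plasmacytoid one.

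The fresh library held a small cluster, number 26, of 0.663% (0.498 to 0.864) of its cells, with IRF8, CPVL and LYZ among the leading genes. After thinning LYZ was found in 51 of 52 of these cells, 98.1% (89.7 to 99.95), SPI1 in 65.4%, CD86 in 21.2%, DNTT in 5.77% and CD34 in 0 of 52 cells, while without thinning DNTT was found in 50% (36.1 to 63.9) and CD34 in 12.96% (5.37 to 24.9). Clustered alone, the fresh library had 1.56% (1.301 to 1.85) plasmacytoid dendritic cell-like cells. Of all fresh cells 25 had at least 3 plasmacytoid dendritic cell markers, 18 plasma cell, 10 dendritic cell and 9 monocyte or macrophage markers. Whether the cultures' myeloid-like cells grew out of such cells or came from blasts was not tested. Clusters 22, 25 and 27 had median mitochondrial shares of 0.109%, 0.0603% and 0.0496%, with median UMIs of 5126, 3420.5 and 5346.

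Cluster 7 of the cultures carried DNTT and CD34 with few other B-lymphoid transcripts. After thinning DNTT was found in 44.9% of its cells in the DC culture and 53.5% in the macrophage culture, CD34 in 29.2% and 41.1%, and CD79A in 2.98% and 3.44%, against 91.1%, 36.3% and 39.5% of fresh B-lymphoid-like cells. Free RNA of blasts is argued against, since the DNTT share was at least 46.9 times that of myeloid-like cells of the same culture, and so is a blast and a myeloid-like cell in 1 droplet, with a LYZ share at most 0.105 times that of myeloid-like cells. Lower depth does not account for the few CD79A and VPREB1 UMIs. At equal depth their shares were at most 0.08701 times those of fresh B-lymphoid-like cells. Before thinning the median cell of cluster 7 had 15505 UMIs, against 11612 in the fresh library. The pattern was picked for its few B-lymphoid transcripts, so these shares do not tell what the cells are. The cells of cluster 7 may be blasts that differ from the fresh ones, or other DNTT and CD34 positive marrow cells. Neither their selection nor a change in culture was tested.

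Interferon response genes were not confined to the myeloid-like cells of the cultures, since in the other classes and clusters of at least 100 cells the median gene stood at 54.7% to 157% of its CPM in myeloid-like cells of the same culture, and in B-lymphoid-like cells of the DC culture at 81.8%, where CCL17 stood at 2.74%. Free RNA of myeloid-like cells is argued against in the named classes and cluster 7, where the interferon genes stood at least 11.7 times higher than the reference transcript, CCL17 or C1QA, but over all classes it stays open because the lowest ratio was 0.634, in cluster 25, whose own C1QA was at 132% of the myeloid-like level. The scaling of the totals is argued against by a lowest median log2 ratio of 3.38 over both cultures and all scalings. A different mix of cell types stays open, since the median of 2.79 within B-lymphoid-like cells compares different clusters, and 2.56% of these cells of the DC culture lay in clusters with at least 100 fresh cells. Culture itself, the cytokines and the handling of the fresh cells differed together and could not be separated, so a response to any of them is open and may be the source.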
